A study of Homo sapiens with 24 samples.

How the data were processed

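RNA was measured by sequencing in HEK293, an established line of human embryonic kidney cells, here grown in suspension in bioreactors and transfected with plasmids so that the cells made recombinant adeno-associated virus (rAAV), a vector used to deliver genes. Per the labels, 3 bioreactors were each sampled at 8 times, namely 0 h (just before the plasmids were added) and 3 h, 6 h, 12 h, 24 h, 36 h, 48 h and 72 h after transfection, which gave 24 libraries and 3 libraries per time. Per the labels' protocols, total RNA was extracted and mRNA was enriched by poly(A) selection. Whether the libraries kept strand was not given in the sources used here.

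Each library had a deposited table of estimated counts (fragments assigned to each of 177816 RefSeq transcripts, not normalized) and of TPM (each transcript's length-corrected share of the library), both written by kallisto, a program that assigns reads to transcripts without aligning them to the genome. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36 and quantified with kallisto 0.44.0 on GRCh38. Per the deposited run records, the version was kallisto 0.42.5, 6 FASTQ files were read per library, no bootstraps were drawn, and the index was built on RefSeq transcripts of the same assembly, so the 2 sources give different versions. The deposited TPM values were not used in a test. A further deposited table per library held the same values (largest relative difference 5.0e-06) and was not used. kallisto shares a read among transcripts of the same sequence, so values of near-identical paralogs (many histone genes, HSPA1A and HSPA1B) and of genes that overlap on the chromosome are uncertain as to which copy they come from. No plasmid or vector sequence and no mitochondrially encoded transcript stood in the index.

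Transcripts were matched to genes of the RefSeq annotation of GRCh38.p14 by accession. Of the 177816 transcripts, 169405 matched with their version, 555 matched without it and 7856 did not match, which left 95.58% matched to 41578 genes and 98.8% to 99.2% of the assigned fragments of each library on matched genes. Estimated counts were summed per gene and rounded to whole numbers. Each library held 86865376 to 114749044 read pairs, of which 68468057 to 99521362 were assigned to transcripts.

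Genes with low counts were removed with edgeR's filterByExpr, which left 22888 genes. Counts were scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) in 1 robust fit over all 24 libraries with the time as the only factor. Each later time was compared with 0 h, 72 h was compared with 24 h, and an overall test asked which genes differed among the 8 times. Adjusted p values are Benjamini-Hochberg values over the genes tested in a comparison, and a gene was called at an adjusted p under 0.05. The SE of a log2 change was back-calculated from that test, as the absolute change divided by the square root of its F value. Levels are given as CPM (counts scaled to the effective library size), and log2 CPM values used a prior count of 2. Where a gene had no count at 0 h, its fold was set against a floor of 3 counts over the 3 libraries and is a lower bound. With 1 to 3 counts at 0 h the ratio is given with a 95% counting interval. Such intervals and floors cover counting error only, since PCR copies are not separate molecules.

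The sampled bioreactors are numbered in the labels, so a number links the libraries of 1 culture over time. The deviations of 2 libraries of the same bioreactor from their time means correlated with a median of 0.108 over 84 pairs (range -0.087 to 0.437), against a median of -0.052 between bioreactors. A fit with the bioreactor as a block was therefore run as an alternative. The replicates came from separate cultures, but each culture gave a library at every time. Counts of replicates at 1 time differed by more than sampling noise in every pair, so none was taken as the same library sequenced again. This cannot tell 2 cultures from 2 preparations of 1 culture, which rests on the labels.

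Gene lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The 29 lists held 766 genes, with 17 genes in more than 1 list. They were interferon genes, interferon-stimulated genes, inflammatory and NF-kB target genes, nucleic acid sensing and signalling, antigen presentation class I, endoplasmic reticulum chaperones, integrated stress response (ATF4 targets), cytosolic heat shock, immediate early genes, p53 targets, apoptosis, S phase genes, G2 and M phase genes, replication-dependent histones, cholesterol biosynthesis, fatty acid synthesis, hypoxia, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, ribosome biogenesis, lysosome and autophagy, metallothioneins, oxidative stress (NRF2 targets), DNA damage signalling and repair, blood cell markers, fibroblast and endothelial markers, and HEK293 lineage genes (neuronal and early kidney). The 27 lists with members past the filter were tested with camera, which compares the members with all other genes, at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over 189 list-by-time tests and separately for 72 h against 24 h. Camera was repeated with the correlation estimated from the data, and members were also adjusted over the list alone. List medians at a time are medians of the members' fitted log2 changes. Medians per bioreactor or library are instead medians of differences in log2 CPM from the 0 h library of the same bioreactor. Medians compared under other scalings also differ from the fitted ones. For interferon-stimulated genes at 72 h they are 1.538 with TMM against 1.769 fitted.

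Genes were named by a rule that took, for each later time against 0 h, the 10 called protein-coding genes with the largest rise and the 8 with the largest fall among those with a mean of at least 5 CPM (over all libraries or over that time) and the same direction in all 3 bioreactors. For each list it took up to 4 called members with the largest change at the time with most calls, and the member with the largest change the other way. It also took 10 fixed genes (IFNB1, ISG15, IFIT1, CXCL10, CXCL8, NFKBIA, HSPA5, DDIT3, CDKN1A and MKI67) and 5 rises and 5 falls at 72 h against 24 h. The rule named 179 genes, and those that mattered most are given in the text.

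The tests were checked on simulated counts with 200 changed genes, all protein-coding with a mean of at least 1 CPM. Counts were drawn independently, with no bioreactor effect and no correlation between genes. The rates below therefore do not cover such effects, rarer genes or data in which far more genes change. For 72 h against 0 h (22453 genes), edgeR recovered 59.7% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 100% of those changed 4-fold, and 7.8% of its calls were unchanged genes. For 3 h against 0 h (22417 genes), it recovered 58.2%, 94% and 97%, and 5.7% of its calls were unchanged genes. DESeq2's Wald test recovered 73.1%, 89.6% and 100% at 72 h with 13.4% of calls on unchanged genes.

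The alternatives were DESeq2's size factors, no filter, a filter of at least 1 CPM in 12 libraries, the bioreactor block, transcript length offsets, protein-coding genes alone, a 2-fold minimum, DESeq2 1.42.0 with its Wald test, a fit of only the 6 libraries compared, each bioreactor and each library left out in turn, camera with an estimated correlation, fry, and lists without shared genes. Chosen after seeing the data were a fit without the libraries rich in ribosomal RNA (rRNA), a fit without rRNA genes, and direct contrasts between later times. Chance was assessed by counting calls in all 10 splits of the 6 libraries of a comparison into 3 and 3, in 100 regroupings of the 24 libraries and, added after the data were seen, in 100 orders of the times within each bioreactor.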

Results

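The series follows suspension HEK293 cells from just before plasmid transfection to 72 h of rAAV production, and its title names antiviral and inflammatory responses as the subject. The 24 libraries fall into 8 times with 3 bioreactors each. Each library held 86865376 to 114749044 read pairs, of which 68468057 to 99521362 were assigned to transcripts. No culture without plasmids was analysed here, so the time in culture and the time since transfection cannot be separated in any comparison. The first principal component of log2 CPM took 32.3% of the variance and the second 12.4%. The share of read pairs that matched no transcript of the index was 8.39% ± 0.16 (SD, n = 3) at 0 h, 10.7% ± 0.202 at 6 h and 18.6% ± 1.12 at 72 h. Fragments on 53 rRNA genes made up 12.4% to 21.8% of gene fragments in 5 libraries, against 0.75% to 1.77% in the other 19. These 5 were the libraries of bioreactor 2 at 24, 36 and 72 h and of bioreactor 3 at 24 and 48 h. Every gene given below with an adjusted p from edgeR's quasi-likelihood test under 0.05 moved in the same direction in all 3 bioreactors.

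**Figure D1:**
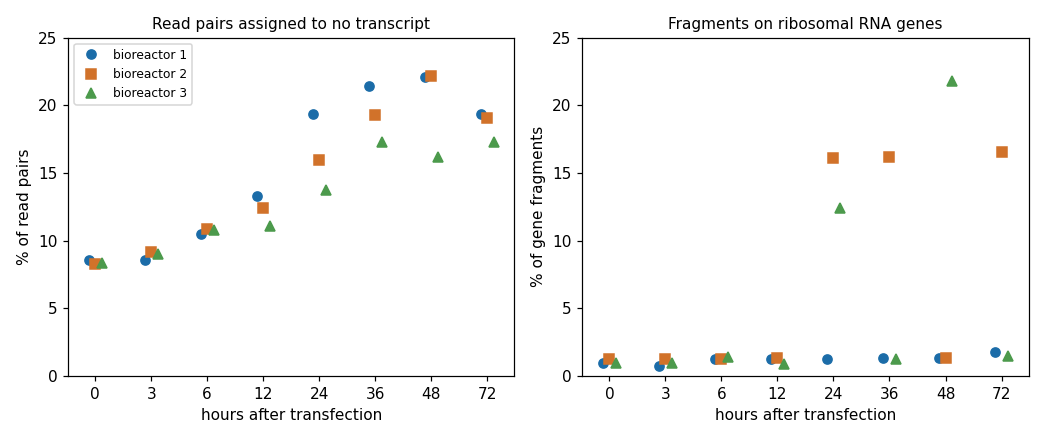
Percent of read pairs assigned to no transcript (left) and percent of gene fragments on rRNA genes (right) in each of the 24 libraries, against hours after transfection, with 1 mark per bioreactor. The unassigned share was 8.39% on average at 0 h and 18.6% at 72 h, and 5 libraries from 24 h on held 12.4% to 21.8% of fragments on rRNA genes.

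Over the whole time course, 11133 of 22888 tested genes (48.6%) differed among the 8 times, and 3095 of them changed by at least 2-fold. The number of genes that differed from 0 h was 525 at 3 h, 3962 at 6 h, 4528 at 12 h, 3739 at 24 h, 3572 at 36 h, 5945 at 48 h and 9648 at 72 h. Rises and falls were near balance in number from 6 h on, but most of the larger changes were rises. At 72 h, 4947 genes rose and 4701 fell, and of those that changed by at least 2-fold 2367 rose and 537 fell. Of the 189 tests of a gene list at a time, 90 passed. With an estimated correlation in place of the preset value only 1 passed, the immediate early genes at 3 h, and for the other list results that passed and are described here that p is given beside the result.

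**Figure D2:**
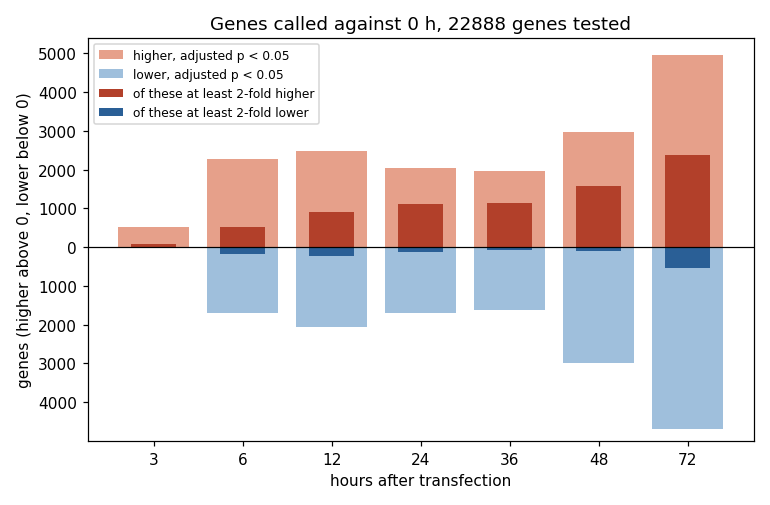
Number of genes higher (upward bars) and lower (downward bars) than at 0 h at each later time, at an adjusted p under 0.05 in edgeR's quasi-likelihood test of 22888 genes, 3 libraries per time. The darker part of each bar holds genes that changed by at least 2-fold, which at 72 h were 2367 higher and 537 lower.

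The earliest comparison, 3 h against 0 h, was almost one-sided, with 516 genes higher and 9 lower. The immediate early genes, transcription factors and other regulators induced within minutes to hours of a stimulus, led the rise, with 20 of 26 measured members higher and 24 when adjusted over the list alone. FOSB, a partner of JUN in the AP-1 transcription factor (chromosome 19, 45467996 to 45475179 in GRCh38.p14), went from 1.10 ± 0.585 to 25.9 ± 4.16 CPM (SD, n = 3), a log2 change of 4.57 ± 0.40 (SE, adjusted p = 6.67e-07). EGR3 rose by 4.56 ± 0.39 (adjusted p = 8.99e-08), ARC by 3.30 ± 0.36 (1.38e-05), JUN by 2.42 ± 0.15 (6.95e-10) and IER2 by 2.34 ± 0.17 (3.29e-09). Outside the list, SH2D3C, a signalling adaptor, rose by 3.42 ± 0.31 (2.15e-07), and GADD45B, a stress-inducible regulator of growth arrest, rose by 2.31 ± 0.21 (2.96e-07). Among p53 targets 6 of 25 rose (8 adjusted over the list alone), with GADD45A at 0.85. The list median of immediate early genes was 1.32 (camera adjusted p = 4.98e-53, and adjusted p = 0.00386 with an estimated correlation). That of p53 targets was 0.26 (2.49e-06, and adjusted p = 0.462 with an estimated correlation).

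Other lists passed at 3 h with few called members or none. Above 0 h were the inflammatory and NF-kB target genes, 2 of 35 higher (6 higher and 1 lower adjusted over the list alone, median 0.17, camera adjusted p = 0.00334, and adjusted p = 0.407 with an estimated correlation), and ribosome biogenesis, 1 of 26 (4 adjusted over the list alone, 0.12, 0.00792, and adjusted p = 0.718 with an estimated correlation). So were apoptosis genes, 3 of 25 (3 adjusted over the list alone, 0.10, 0.00792, and adjusted p = 0.236 with an estimated correlation), and histones, 1 of 31 (2 adjusted over the list alone, 0.52, 0.00213, and adjusted p = 0.649 with an estimated correlation). Below 0 h without a called member were the cytosolic ribosomal proteins (median -0.22, 5.21e-11, and adjusted p = 0.646 with an estimated correlation) and nuclear-encoded oxidative phosphorylation (-0.19, 7.71e-07, and adjusted p = 0.629 with an estimated correlation). Bioreactor 1 did not share these shifts, with medians in bioreactors 1, 2 and 3 of 0.002, -0.368 and -0.281 for the ribosomal proteins and 0.007, -0.315 and -0.269 for oxidative phosphorylation. Glycolysis (-0.21, 0.000115, and adjusted p = 0.472 with an estimated correlation), G2 and M phase genes (-0.11, 0.00117, and adjusted p = 0.557 with an estimated correlation) and NRF2 targets (-0.12, 0.0316, and adjusted p = 0.623 with an estimated correlation) had none either. Of 3 metallothioneins 1 was lower (3 adjusted over the list alone, -0.53, 0.0022, and adjusted p = 0.337 with an estimated correlation).

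The count of 525 at 3 h depended on single libraries, with 220 calls without the 3 h library of bioreactor 1, 288 without the 0 h library of bioreactor 2 and 334 without the 0 h library of bioreactor 3. It was 976 with a bioreactor term, 847 by DESeq2's Wald test and 70 at a 2-fold minimum.

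At 6 h and 12 h more genes of the inflammatory and ribosome biogenesis lists were called higher than at 3 h. CXCL8, a chemokine that attracts neutrophils (chromosome 4, 73740569 to 73743716), rose by 3.41 ± 0.55 at 6 h (adjusted p = 0.00042), from 0.445 ± 0.088 to 4.74 ± 0.997 CPM (SD, n = 3). RELB, a subunit of NF-kB, rose by 2.53 ± 0.20 (1.84e-08), and MAFF, a small Maf transcription factor, by 2.62 ± 0.21 (1.71e-08). The largest rises at 6 h included CGA, the common alpha subunit of the glycoprotein hormones (3.54 ± 0.21, 1.51e-10), INHBA, a subunit of activin A (3.36 ± 0.42, 2.32e-05), and DNAH17, an axonemal dynein heavy chain (2.95 ± 0.34, 1.57e-05). CGAS, the sensor of DNA in the cytosol (chromosome 6, 73423711 to 73452297), rose by 3.03 ± 0.56 (0.000683) from 0.071 CPM. NFKBIA, the inhibitor of NF-kB that NF-kB itself induces, rose by 0.65 ± 0.15 (0.00419). By 12 h CGA stood at 4.19 (4.82e-12), DNAH17 at 4.18 and TNFRSF9, a receptor of the TNF receptor family, at 3.46 (0.00315), and IFIT2, an interferon-stimulated gene, had risen by 2.24 ± 0.36 (0.000267). TNFRSF9 was not called without bioreactor 2 (3.292, 0.0963).

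Of the 35 inflammatory and NF-kB target genes measured, 12 were higher and 1 lower at 6 h (15 and 1 adjusted over the list alone), and 14 were higher and 1 lower at 12 h (15 and 1). The list median was 0.65 at 6 h (camera adjusted p = 2.49e-06, and adjusted p = 0.145 with an estimated correlation) and 0.66 at 12 h (1.13e-06, and adjusted p = 0.145 with an estimated correlation). Immediate early genes were still high at 6 h, with 18 of 26 higher (20 higher and 1 lower adjusted over the list alone, 9.05e-13, and adjusted p = 0.194 with an estimated correlation). Fewer were called at 24 h, 5 higher and 2 lower (median 0.265). More were called again later, 13 higher and 1 lower at 48 h (0.568) and 15 higher and 2 lower at 72 h (0.751). Ribosome biogenesis genes rose at 6 h and at 12 h, 17 of 26 each (adjusted over the list alone, 18 rose and 1 fell at 6 h and 18 rose at 12 h). RRP12 stood at 1.23 and NOP2 at 0.91 at 6 h (list 3.11e-07, and adjusted p = 0.472 with an estimated correlation). The list p was 7.48e-09 at 12 h (adjusted p = 0.466 with an estimated correlation). Transcripts of the ribosomal proteins themselves moved the other way at 6 h, where 16 of 75 fell and 32 did so adjusted over the list alone (median -0.39, 7.95e-14, and adjusted p = 0.582 with an estimated correlation). With a bioreactor term 53 of the 75 fell. S phase genes rose at 12 h, 13 of 37 (17 adjusted over the list alone, 6.08e-05, and adjusted p = 0.557 with an estimated correlation). E2F8 stood at 0.74.

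At 6 h, 7 of 18 glycolysis genes were lower and 1, the lactate exporter SLC16A3 at 1.12, was higher (13 and 1 adjusted over the list alone, camera adjusted p = 0.000407, and adjusted p = 0.502 with an estimated correlation). Among 40 nuclear-encoded oxidative phosphorylation genes 6 fell (6 adjusted over the list alone, 1.85e-06, and adjusted p = 0.646 with an estimated correlation). With a bioreactor term 23 of these 40 fell at 6 h, and 12 of the 18 glycolysis genes. Of 19 hypoxia genes 6 fell, and the list passed without a bioreactor term (0.0365) and missed the threshold with it (0.0527), and adjusted p = 0.557 with an estimated correlation. Adjusted over the list alone, 7 hypoxia genes were lower and 1 was higher. All 3 measured metallothioneins, metal-binding proteins, were lower at 6 h and at each later time, with MT1X at -0.71 at 6 h (3 adjusted over the list alone, 0.00522, and adjusted p = 0.407 with an estimated correlation). Of 24 cholesterol biosynthesis genes 11 fell by 12 h (12 adjusted over the list alone, 2.29e-06, and adjusted p = 0.502 with an estimated correlation). SQLE, an early enzyme of the sterol branch, stood at -0.83. Antigen presentation genes fell in part at 6 h, 3 of 17 (3 adjusted over the list alone, 7 with a bioreactor term, 0.00473, and adjusted p = 0.47 with an estimated correlation). TAPBP stood at -0.44.

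In all, 2274 genes were higher and 1688 lower at 6 h, and 2469 were higher and 2059 lower at 12 h. The 6 h count of 3962 fell to 2038 without the 6 h library of bioreactor 1, to 2098 without the 0 h library of bioreactor 2 and to 2300 without the 6 h library of bioreactor 2. It was 6098 with a bioreactor term and 6139 in a fit of the 6 libraries alone. The 12 h count of 4528 fell to 2169 without the 12 h library of bioreactor 1, to 2389 without that of bioreactor 2 and to 2548 without the 0 h library of bioreactor 2.

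**Figure D3:**
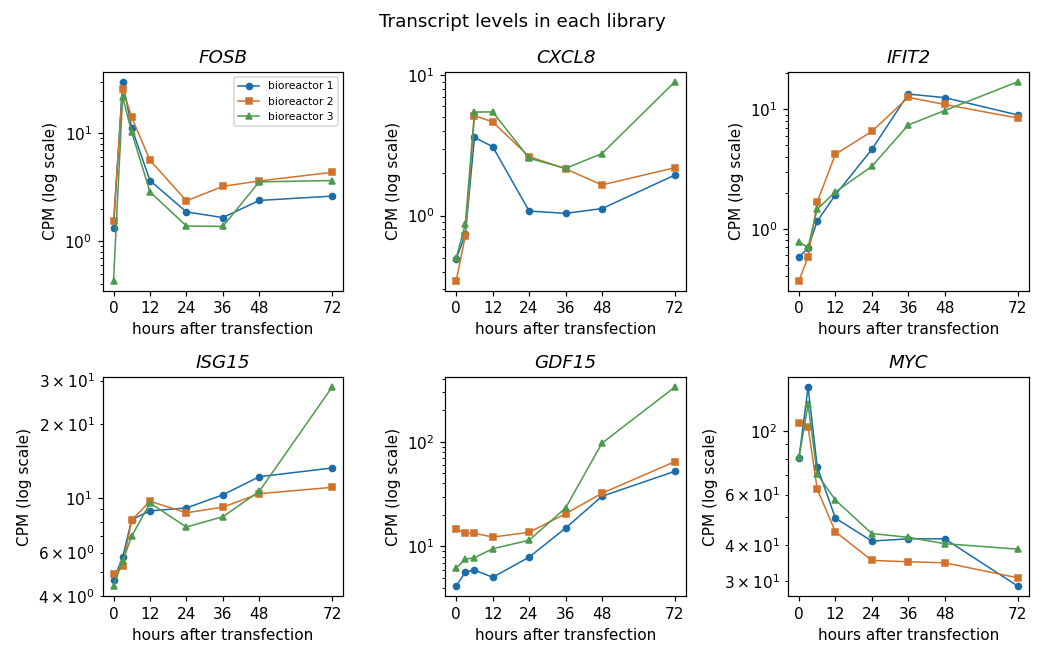
CPM (log axis) of FOSB, CXCL8, IFIT2, ISG15, GDF15 and MYC against hours after transfection, with 1 line per bioreactor. FOSB was highest at 3 h (25.9 CPM on average), CXCL8 went from 0.445 CPM at 0 h to 4.74 CPM at 6 h, IFIT2 stood at 11.1 CPM at 36 h and 11.4 CPM at 72 h, and MYC fell from 89.2 CPM at 0 h to 32.8 CPM at 72 h.

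By 24 h the replication-dependent histone genes, whose transcripts normally end in a stem-loop without a poly(A) tail, were the most shifted list. Of 31 measured, 27 were higher (30 adjusted over the list alone), and the median log2 change was 2.62. H2BC5 rose by 3.08 ± 0.24 (adjusted p = 1.42e-08), H1-2 by 2.49, H2AC18 by 2.60 and H3C4 (chromosome 6, 26196784 to 26199293) by 4.56 ± 0.47 (4.91e-07). The list passed at 24 h (camera adjusted p = 3.14e-23, and adjusted p = 0.145 with an estimated correlation) and at 36 h, where 21 were higher (28 adjusted over the list alone, 2.82e-19, and adjusted p = 0.194 with an estimated correlation). Both 24 h libraries of bioreactors 2 and 3 and the 36 h library of bioreactor 2 were rich in rRNA, and the histone medians at 24 h were 1.31, 3.05 and 2.42 in bioreactors 1, 2 and 3. Without the rich libraries 16 histone genes were called at 24 h, in a fit with 1 library left at that time, which was assumed to vary like those of the other times.

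Single interferon-stimulated and cytokine genes were high in this period. IFIT2 (chromosome 10, 89302046 to 89309271) rose by 3.06 ± 0.37 at 24 h (adjusted p = 8.14e-06) and by 4.27 at 36 h, from 0.574 ± 0.202 CPM at 0 h to 11.1 ± 3.25 CPM (SD, n = 3). CCL5, a chemokine for T cells and monocytes, rose by 4.41 ± 0.49 at 24 h (1.34e-06) from 0.036 CPM. ISG15, a ubiquitin-like protein induced by interferon, rose by 0.86 ± 0.21 (0.00681). As a list, the 55 interferon-stimulated genes measured had 8 members higher and 2 lower at 24 h (8 and 2 adjusted over the list alone, median 0.10, camera adjusted p = 0.171) and 9 higher and 1 lower at 36 h (9 and 1, median 0.21, 0.00326, and adjusted p = 0.728 with an estimated correlation). Inflammatory genes had 11 higher and 1 lower at 24 h (12 and 1 adjusted over the list alone, 0.000674, and adjusted p = 0.31 with an estimated correlation). CGA stayed at 4.23 ± 0.21 (4.08e-12), DNAH17 at 4.39, and DHRS2, a mitochondrial reductase, had risen by 2.94. Blood cell markers had 4 of 11 members higher at 24 h (4 adjusted over the list alone, 0.0054, and adjusted p = 0.194 with an estimated correlation). ITGAM stood at 4.38.

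Cholesterol biosynthesis genes were lower at 24 h, 13 of 24 (17 adjusted over the list alone, camera adjusted p = 1.64e-07, and adjusted p = 0.466 with an estimated correlation). SQLE stood at -0.71 (adjusted p = 0.00655), LSS at -0.70 (0.00287) and DHCR7 at -0.68. MYC, a transcription factor that drives growth, fell by 1.15 ± 0.14 (5.55e-06), and SLC33A2, ABHD14B and GAPDHS fell by 1.51, 1.24 and 1.14. Of 22 endoplasmic reticulum chaperone genes 4 rose and 1 fell (5 and 1 adjusted over the list alone, 0.00536, and adjusted p = 0.703 with an estimated correlation). XBP1, the transcription factor of the unfolded protein response, stood at 1.19. At 36 h 3 of 12 fatty acid synthesis genes fell (5 adjusted over the list alone), and the list passed without a bioreactor term (0.0437, and adjusted p = 0.515 with an estimated correlation) and missed the threshold with it (0.0633). The cholesterol count depended on single libraries, with 3 calls without the 24 h library of bioreactor 2, 4 without that of bioreactor 1 and 4 without the 0 h library of bioreactor 2, and it was 4 without the libraries rich in rRNA, with 1 library left at 24 h.

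In all, 2035 genes were higher and 1704 lower at 24 h, and 1957 were higher and 1615 lower at 36 h. Without the libraries rich in rRNA these totals were 1558 at 24 h, with 1 library left and its spread taken from the other times, and 2369 at 36 h, with 2 left. The 24 h count of 3739 was 1905 without the 24 h library of bioreactor 2, 2108 without that of bioreactor 1, 2436 without the 0 h library of bioreactor 2 and 2470 without that of bioreactor 3. The 36 h count of 3572 was 1851 without the 36 h library of bioreactor 2, 5398 with a bioreactor term and 2326 with the stricter filter.

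**Figure D4:**
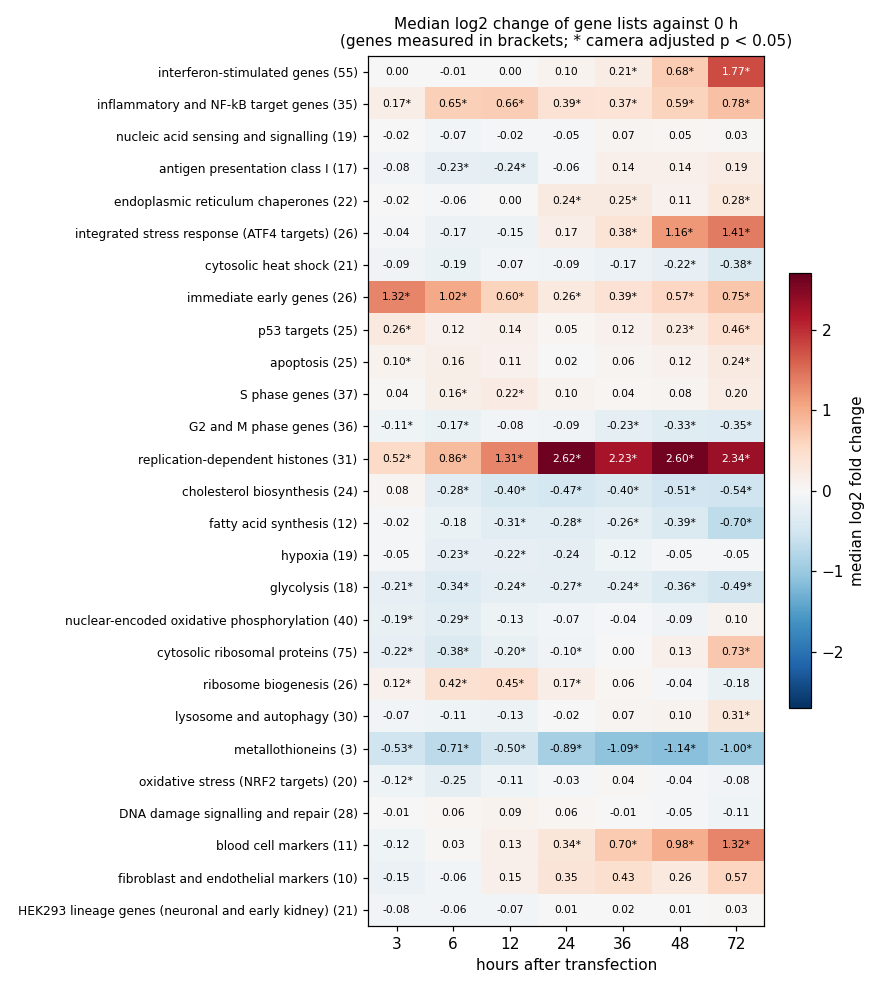
Heat map of the median log2 change from 0 h of each gene list (rows) at each later time (columns, hours), with an asterisk where camera's adjusted p was under 0.05 at the preset correlation. The immediate early genes stand at 1.32 at 3 h, the histones at 2.62 at 24 h, and the interferon-stimulated genes go from 0.10 at 24 h to 1.77 at 72 h.

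At 48 h the integrated stress response, in which the transcription factor ATF4 raises genes of amino acid supply and cell stress, joined the rising lists, with 14 of 26 members higher (17 adjusted over the list alone). NUPR1, a stress-induced chromatin regulator, rose by 2.71 (adjusted p = 0.00177), GDF15, a secreted stress cytokine (chromosome 19, 18386158 to 18389176), by 2.67 (0.0126), FGF21, a secreted metabolic hormone, by 3.30 (0.0018), and DDIT3, which encodes the CHOP transcription factor, by 2.03 ± 0.38 (0.000849). The rise of GDF15 was uneven, from 4.19, 14.7 and 6.23 CPM at 0 h to 30.2, 32.3 and 97.2 CPM in bioreactors 1, 2 and 3. The last of these values is from the library rich in rRNA. Interferon-stimulated genes had 15 members higher and 1 lower (19 and 2 adjusted over the list alone, median 0.68), with IFI44 at 3.86 (0.000801). Of 36 G2 and M phase genes 21 fell (22 fell and 2 rose adjusted over the list alone, median -0.33). The p53 target TP53I3 rose by 1.53, and FASN, the fatty acid synthase, fell by 1.18 (0.000239).

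Camera gave an adjusted p of 9.86e-07 for the stress response at 48 h (adjusted p = 0.557 with an estimated correlation), 9.87e-06 for the interferon-stimulated genes (0.56) and 2.29e-06 for the G2 and M phase genes (0.466), where the p in parentheses is the adjusted p with an estimated correlation. Histones stayed high (27 of 31, 29 adjusted over the list alone, 5e-19, and adjusted p = 0.194 with an estimated correlation). In all, 2961 genes were higher and 2984 lower. The total of 5945 was 3781 without the 48 h library of bioreactor 3, which was rich in rRNA and the only such library at this time, and 3922 without every rich library. The stress response count was 9 without that same library.

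The last comparison, 72 h against 0 h, called more interferon-stimulated genes than any earlier time. Of 55 interferon-stimulated genes measured, 47 rose and 2 fell (49 and 2 adjusted over the list alone), with a median log2 change of 1.77, also with RSAD2 held at its bound. IFI44 rose by 6.01 ± 0.71 (adjusted p = 1.83e-06), IFI27 by 5.01 ± 0.65 (1.02e-05), IFIT2 by 4.31 ± 0.37 (4.32e-08), IFIT3 by 4.18 ± 0.47 (2.02e-06), IFIT1 by 2.49 ± 0.38 (4.03e-05) and ISG15 by 1.91 ± 0.21 (4.6e-07). STAT2, a subunit of the interferon-activated transcription factor, fell by 0.77 ± 0.12 (1.67e-05). RSAD2 (viperin, an antiviral enzyme) had no count at 0 h and 19, 15 and 94 counts at 72 h, at least 47.9-fold higher. CXCL10 had 3 counts at 0 h and was higher by a ratio of 20.6 (95% interval 6.69 to 103). Of the interferon genes themselves none passed the filter. IFNB1, the gene of interferon beta, had no count at 0 h and 8, 9 and 29 counts at 72 h, at least 17.2-fold higher. The change was uneven between bioreactors, with list medians of 1.01, 0.98 and 2.49 in bioreactors 1, 2 and 3 and IFIT1 at 21.1 ± 18.0 CPM (SD, n = 3) against 3.73 ± 0.721 at 0 h. Camera gave 1.66e-13 for the list (adjusted p = 0.407 with an estimated correlation).

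Inflammatory genes had 20 of 35 members higher and 2 lower at 72 h (22 and 2 adjusted over the list alone, median 0.78, camera adjusted p = 0.000107, and adjusted p = 0.236 with an estimated correlation). CCL5 rose by 5.93 ± 0.47 (adjusted p = 3.24e-09), CXCL8 by 3.28 ± 0.55 (0.000128) and C3, the central complement component, by 2.98. The cytokine genes IL6 and IL1B had 75 and 52 counts in total over the 24 libraries and were not tested. Among 19 genes of nucleic acid sensing and signalling 5 rose and 5 fell (5 and 6 adjusted over the list alone, 0.933, and adjusted p = 0.993 with an estimated correlation). The risers included CGAS at 3.32, IRF7 at 2.40, and RIGI, which encodes the RNA sensor RIG-I, at 1.77. IRF7 and RIGI also stand in the interferon-stimulated list, so their rise is not separate from that result. Class I antigen presentation genes had 6 higher and 2 lower (7 and 2 adjusted over the list alone, 0.195, and adjusted p = 0.733 with an estimated correlation). B2M stood at 0.79 and the peptide transporter subunit TAP2 at -1.10. The number of inflammatory genes called higher was 11 with the stricter filter and 13 at a 2-fold minimum. Markers of blood cells were also higher at 72 h, 7 of 11 measured (7 adjusted over the list alone, 0.00113, and adjusted p = 0.145 with an estimated correlation). LAPTM5, a lysosomal membrane protein of blood cells, stood at 4.17 ± 0.60 (1.05e-05) and ITGAM, the integrin alpha M chain, at 3.74 ± 0.45 (1.11e-06), both from below 0.1 CPM at 0 h.

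Stress lists split at 72 h. Of 26 integrated stress response genes 20 rose (23 adjusted over the list alone, median 1.41, camera adjusted p = 1.6e-07, and adjusted p = 0.546 with an estimated correlation). GDF15 rose by 4.17 ± 0.76 (adjusted p = 0.000407), NUPR1 by 4.13 ± 0.57 (3.06e-05), FGF21 by 4.29 ± 0.69 (5.95e-05) and DDIT3 by 2.77 ± 0.39 (2.23e-05). Endoplasmic reticulum chaperones had 9 of 22 higher and 1 lower (10 and 1 adjusted over the list alone, 0.018, and adjusted p = 0.77 with an estimated correlation). DNAJB9 stood at 2.23, HERPUD1 at 1.91 and XBP1 at 1.68 ± 0.30 (0.000193). In a fit of the 6 libraries alone DNAJB9 (0.0849), HERPUD1 (0.087) and GDF15 (0.0555) were not called. HSPA5, the main chaperone of this compartment, did not pass (0.51 ± 0.21, 0.0517). Of 25 p53 targets 15 rose (16 adjusted over the list alone, 0.000675, and adjusted p = 0.546 with an estimated correlation). TP53I3 stood at 2.07 ± 0.19 (3.91e-08), MDM2 at 1.35 ± 0.18 (3.94e-06) and CDKN1A, the p21 cell cycle inhibitor, at 0.80 ± 0.14 (6.87e-05). Of 25 apoptosis genes 10 rose and 1 fell (10 and 1 adjusted over the list alone, 0.0365, and adjusted p = 0.375 with an estimated correlation). BIK stood at 1.37, PMAIP1 at 1.24 and the death receptor FAS at 1.11. Cytosolic heat shock genes went the other way, 11 of 21 lower and 3 higher (12 and 3 adjusted over the list alone, 0.0197, and adjusted p = 0.649 with an estimated correlation). HSPA1A stood at -2.31 and CRYAB, a small heat shock protein, at 1.62. The stress response count of 20 was 13 without the 72 h library of bioreactor 3, and the stress response medians were 0.99, 0.68 and 2.35 in bioreactors 1, 2 and 3.

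**Figure D5:**
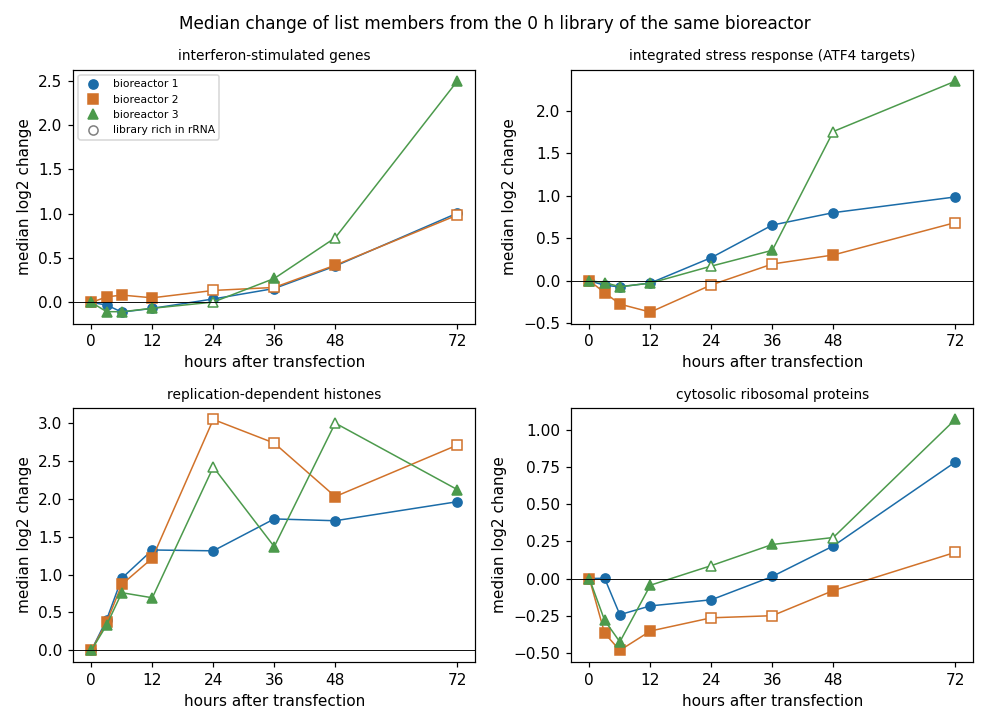
Median log2 change of 4 gene lists (interferon-stimulated genes, integrated stress response, histones, cytosolic ribosomal proteins) in each later library from the 0 h library of the same bioreactor, against hours after transfection, with open marks for the 5 libraries rich in rRNA. At 72 h the interferon-stimulated genes stand at 1.01, 0.98 and 2.49 in bioreactors 1, 2 and 3.

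At 72 h the lists of lipid synthesis, glycolysis and the G2 and M phases had more members lower than higher. Of 24 cholesterol biosynthesis genes 15 fell and 1 rose (17 and 1 adjusted over the list alone, median -0.54, camera adjusted p = 7.07e-05, and adjusted p = 0.557 with an estimated correlation). LSS, the lanosterol synthase, stood at -1.30 ± 0.15 (adjusted p = 9.35e-07) and DHCR7 and SQLE at -1.06 and -1.01. Of 12 fatty acid synthesis genes 8 fell and 1 rose (9 and 1 adjusted over the list alone, 0.00177, and adjusted p = 0.316 with an estimated correlation). FASN stood at -1.66 ± 0.21 (2.32e-06), SCD at -1.15 and SREBF1 at -1.08. Of 18 glycolysis genes 14 fell and 1 rose (14 and 1 adjusted over the list alone, 7.3e-05, and adjusted p = 0.466 with an estimated correlation), with the phosphofructokinase genes PFKM at -0.92 (9.89e-06) and PFKL at -0.87 (1.92e-06). G2 and M phase genes had 21 of 36 lower and 4 higher (21 and 4 adjusted over the list alone, 0.000676, and adjusted p = 0.557 with an estimated correlation), with the proliferation marker MKI67 at -1.11 ± 0.25 (0.00134), which was not called without bioreactor 1 (-1.037, 0.0522). S phase genes had 16 of 37 higher and 5 lower (17 and 6 adjusted over the list alone, 0.12), with CCNE2, a cyclin of the G1 to S transition, at 1.44 (1.46e-08). The G1 cyclin CCND1 fell by 1.71 ± 0.26 (4.47e-05). The glycolysis count was 7 without the 72 h library of bioreactor 3.

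Cytosolic ribosomal protein transcripts, which had fallen in part at 6 h, were higher at 72 h, 66 of 75 (73 adjusted over the list alone, median 0.73, camera adjusted p = 6.98e-13, and adjusted p = 0.607 with an estimated correlation). RPS18 rose by 1.31 ± 0.24 (adjusted p = 2e-04), RPS3A by 1.21, RPL9 by 1.14 and RPS15A by 1.13, and 7 members passed a 2-fold minimum. Medians per bioreactor were 0.78, 0.18 and 1.07, the lowest being that of the library rich in rRNA. Histones stayed high, 25 of 31 (26 adjusted over the list alone, median 2.34, 1.66e-13, and adjusted p = 0.303 with an estimated correlation). Ribosome biogenesis genes, in contrast, had 4 of 26 higher and 9 lower (5 and 9 adjusted over the list alone, 0.149, and adjusted p = 0.902 with an estimated correlation). Lysosome and autophagy genes had 15 of 30 higher and 3 lower (15 and 3 adjusted over the list alone, 0.00826, and adjusted p = 0.557 with an estimated correlation). GPNMB stood at 1.15, NEU1 at 0.90 and GAA, the acid glucosidase, at -1.04.

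The largest single rises at 72 h lay partly outside the lists. CDHR4, a cadherin-related gene (chromosome 3, 49790732 to 49802914), rose by 7.54 ± 0.52 (adjusted p = 1.38e-09), from 0.06 ± 0.017 to 11.5 ± 5.55 CPM (SD, n = 3). The uncharacterised gene LOC124902363 (chromosome 10, 931991 to 936089) rose by 5.99 ± 0.32 (4.53e-11). ELSPBP1 rose by 5.61, STMN4, a neuronal relative of stathmin, by 5.59 ± 0.41 (1.82e-09) and KLHDC7B by 5.48. The largest falls among genes of at least 5 CPM were in SLC33A2 (chromosome 8, 144509070 to 144511213), which fell by 2.83 ± 0.26 (1e-07) from 42.6 to 5.99 CPM, in MYCBP2, a ubiquitin ligase, which fell by 2.54 ± 0.58 (0.00213), and in the heat shock pair HSPA1A and HSPA1B, whose reads cannot be assigned with certainty to either copy. The call of MYCBP2 was lost without bioreactor 1 (-2.59, 0.0719) and in a fit of the 6 libraries alone (-2.525, 0.128). IGFBP5 stood at -1.96, ASIC1 at -1.82 and TXNIP, an inhibitor of thioredoxin, at -1.71. MYC stood at -1.44. The total of 9648 genes stayed within 1.5 times of this value when any single library was left out.

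The comparison of 72 h with 24 h asked what changed late in production, with 2177 genes higher and 2337 lower. Interferon-stimulated genes were higher at 72 h than at 24 h, 45 of 55 (48 adjusted over the list alone, median 1.28, camera adjusted p = 1.18e-21, and adjusted p = 0.241 with an estimated correlation). So were 20 of 26 stress response genes (24 adjusted over the list alone, 3.52e-11, and adjusted p = 0.298 with an estimated correlation) and 73 of 75 ribosomal protein genes (75 adjusted over the list alone, 5.9e-34, and adjusted p = 0.294 with an estimated correlation). Ribosome biogenesis genes were lower, 16 of 26 with 1 higher (17 and 1 adjusted over the list alone, 4.95e-07, and adjusted p = 0.298 with an estimated correlation). CDHR4 rose by 3.84 (adjusted p = 8.73e-06), S100P, a calcium-binding protein, by 5.26 (0.00221), IFI44L by 4.49 (0.000373) and IFI27 by 4.31 (0.000326). TXNIP fell by 1.63 (0.00154) and its relative ARRDC4 by 1.39 (0.000469). Blood cell markers had 4 of 11 members higher (4 adjusted over the list alone, 0.0377, and adjusted p = 0.26 with an estimated correlation), and the list missed the threshold with a bioreactor term (0.0617). In a fit of only the 6 libraries compared 184 genes passed instead of 4514, and of these named genes CDHR4 alone stayed past the threshold. S100P was also not called without bioreactor 1 (5.461, 0.0511). The count was 1744 without the 72 h library of bioreactor 3, 2051 without the 24 h library of bioreactor 1, 2505 without that of bioreactor 2 and 4082 without the libraries rich in rRNA, with 1 library left at 24 h and 2 at 72 h.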

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

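Among the tests in this part, the direct contrasts between later times, the comparison with genes of matched length and the test of scaling were chosen only after the results were seen.

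The share of read pairs that matched no transcript lay above all 3 of the 0 h libraries (8.39% ± 0.16, SD, n = 3) at each time from 6 h on, a signal outside the measured transcripts. It was 10.7% ± 0.202 at 6 h, 12.3% ± 1.09 at 12 h, 16.4% ± 2.84 at 24 h, 19.4% ± 2.07 at 36 h, 20.2% ± 3.43 at 48 h and 18.6% ± 1.12 at 72 h. The later libraries averaged 6.8 percentage points more than the 0 h library of the same bioreactor, and 6 of 512 arrangements of the times within bioreactors gave as large a difference (exact permutation test, two-sided p = 0.0117, smallest possible 0.00195). The share was flagged for lying above the 0 h libraries, so this p largely restates that choice. The reads themselves were not analysed here, so what they match was not tested.

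Contrasts between 2 times were run for lists with at least 20% of members called higher at 1 time and at least 20% called lower at another. The lists and times were picked from the same calls, so each p below largely restates that choice. Ribosomal protein genes were higher at 72 h than at 6 h in 75 of 75 cases (median log2 difference 1.09, camera adjusted p = 5.35e-31, and adjusted p = 0.191 with an estimated correlation). Ribosome biogenesis genes were higher at 6 h than at 72 h in 19 of 26 cases and lower in 1 (0.61, 1.24e-07, and adjusted p = 0.191 with an estimated correlation). DNA damage signalling and repair genes were higher at 12 h than at 72 h in 14 of 28 cases and lower in 2 (0.28, 0.00315, and adjusted p = 0.191 with an estimated correlation). The hypoxia list (0.31) and the fibroblast and endothelial markers (0.44) did not differ in such a contrast past the threshold.

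The higher level of ribosomal protein transcripts at 72 h was weighed against technical explanations, since these transcripts are short and abundant. Each of 72 ribosomal protein genes was matched on effective length to 3 to 5 protein-coding partners (median 604 against 570 bases). The median of the partner medians was 0.119 against 0.728, which argues against length bias. Abundance was matched less closely, with partners at a median of 381.3 CPM against 1036.7, so it is not covered. That match was the last of 3, because the earlier matches had left longer partner genes (medians of 1732 and 1019 bases, with changes of -0.037 and 0.074). A scaling moves all genes alike, so it cannot open a gap between ribosomal protein genes and others. The upper quartile of the partner medians was 0.312, against a lower quartile of 0.455 for single ribosomal protein genes. The list was examined because of that gap, so these quartiles are not a separate test of scaling. Other scalings moved no list median by more than 0.008 at 72 h, so they tested nothing at this time. Cell stress, growth arrest and time in culture may each underlie the pattern, remain untested, and cannot be separated in this design.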

How the results depend on the processing

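Of the fits below, those without the libraries rich in rRNA and without rRNA genes were chosen only after the data were seen. Results for named genes were tallied under the alternatives other than the 2-fold minimum and the changed list tests. A fit with 1 library left out was tallied only for comparisons that used the time of that library. Of these 4743 results, 4411 kept their direction and their side of the threshold, 318 kept the direction but lost the call, 11 gained it and 3 reversed. EGR1 at 72 h reversed from -0.65 to 1.73 without bioreactor 2 and to 1.68 without the 0 h library of bioreactor 2 (range with a bioreactor or library left out -1.44 to 1.73), and BYSL at 72 h went from -0.13 to 0.062 without bioreactor 3 (range -0.265 to 0.062). Counts of calls moved by less than 1.5 times with DESeq2's size factors, transcript length offsets, protein-coding genes alone and rRNA genes left out, and 0 of the 90 list results that passed had a median of another sign under another scaling. The median of all genes moved by at most 0.103, at 48 h with plain totals without rRNA genes. At 72 h no list median moved by more than 0.008, so the scalings tested nothing there. No scaling moved the share of higher calls by over 10 percentage points. The other abundance table holds the same values and was not run.

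With the bioreactor block, 976 genes were called at 3 h, 6098 at 6 h and 5398 at 36 h. The block took the hypoxia list at 6 h to 0.0527, the fatty acid list at 36 h to 0.0633 and the blood markers at 72 h against 24 h to 0.0617. It let the NRF2 targets pass at 6 h (0.0401) and oxidative phosphorylation at 12 h (0.0191) and at 72 h against 24 h (0.00884), and it changed no other list's call. A 2-fold minimum in edgeR's test left 70 genes at 3 h, 691 at 6 h, 1128 at 12 h, 1238 at 24 h, 1215 at 36 h, 1677 at 48 h and 2904 at 72 h, 645 at 72 h against 24 h and 3095 over the course. It also left 1 ribosome biogenesis gene at 12 h, 0 cholesterol genes at 24 h, and, at 72 h, 13 inflammatory, 7 ribosomal protein, 1 G2 and M phase and 0 glycolysis genes, since most list members moved by less than 2-fold. With no filter 8 cholesterol genes passed at 24 h. At least 1 CPM in 12 libraries, which leaves fewer genes of each list, gave 9 inflammatory genes at 12 h and 11 at 72 h, 14 histones at 24 h and 2326 genes at 36 h. DESeq2's Wald test called 847 genes at 3 h, and on simulated counts it made more false calls than edgeR. It gave IFI27 no adjusted p at 72 h. Fits of only the 6 libraries compared gave 6139 genes at 6 h, 184 at 72 h against 24 h, 24 interferon-stimulated genes at 48 h, and 10 stress response and 9 glycolysis genes at 72 h, with fewer samples to estimate the spread. Without the libraries rich in rRNA there were 1558 genes at 24 h, 2369 at 36 h and 3922 at 48 h, with 16 histones and 4 cholesterol genes at 24 h and 8 stress response genes at 48 h. That fit kept 1 library at 24 h, assumed to vary like the libraries of the other times, and 2 at 36 h, at 48 h and at 72 h. Camera with an estimated correlation passed 1 list result instead of 90. Fry, which asks whether a list moves on balance and does not compare it with other genes, passed 76, of which 66 were among the 90. Of the 24 it did not pass, 7 were at 3 h, and others were ribosomal proteins (0.0701), oxidative phosphorylation (0.122) and hypoxia (0.0762) at 6 h, interferon-stimulated genes at 36 h (0.131) and endoplasmic reticulum chaperones at 24 h (0.143) and 72 h (0.0682). It passed fibroblast and endothelial markers at 72 h (0.000209). Without genes shared between lists, apoptosis at 3 h (0.0604) and fatty acid synthesis at 36 h (0.0604) no longer passed, and p53 targets (0.0289) and NRF2 targets (0.0325) passed at 6 h. Where no reason is given, the cause was not tested.

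Leaving out each bioreactor or library gave counts from 37 to 766 at 3 h, 541 to 4518 at 6 h, 735 to 5609 at 12 h, 608 to 4175 at 24 h, 739 to 3535 at 36 h, 2281 to 5319 at 48 h, 6228 to 9693 at 72 h, 711 to 5580 at 72 h against 24 h and 4301 to 11751 over the course. List results ranged from 8 to 20 for immediate early genes at 3 h, 6 to 14 for inflammatory genes and 8 to 19 for ribosome biogenesis at 12 h, 15 to 27 for histones and 0 to 17 for cholesterol genes at 24 h, and 10 to 18 for interferon-stimulated and 9 to 17 for stress response genes at 48 h. At 72 h they ranged from 38 to 49 for interferon-stimulated, 15 to 21 for inflammatory, 13 to 22 for stress response, 29 to 73 for ribosomal protein, 14 to 21 for G2 and M phase and 5 to 15 for glycolysis genes, and list results that passed ranged from 80 to 96. The lowest counts of genes came from leaving out a whole bioreactor, with 2 libraries per time left. At 68468057 to 99521362 fragments per library, the interferon genes had too few counts to pass the filter. How the calls depend on depth was not tested.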

Other observations

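In this part, the tests of the libraries rich in rRNA, of S phase genes and of blood cells were chosen only after the results were seen. The orders of the times within each bioreactor were also added after the data were seen.

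Several lists not described above had called members at 72 h. Of all 22888 tested genes 42.2% were called at this time, 4947 higher and 4701 lower. Counts near that share are not by themselves a shift of a list. Of 10 fibroblast and endothelial markers measured, 3 rose and 2 fell at 72 h (4 and 2 adjusted over the list alone, camera adjusted p = 0.249), with VWF, the von Willebrand factor, at 2.76, PDGFRB at 1.58 and ACTA2, smooth muscle actin, at 0.95. Of 21 genes of the neuronal and early kidney character of HEK293, 4 rose and 7 fell (4 and 8 adjusted over the list alone, 0.776). TUBB3, a neuronal tubulin, rose by 1.42, from 18.8 ± 2.23 to 50.4 ± 2.74 CPM (SD, n = 3), the neuronal MAP2 by 0.92 and the epithelial keratin KRT8 by 0.96, while WT1, a transcription factor of the early kidney, fell by 1.05, a call lost without bioreactor 2 (-0.692, adjusted p = 0.137).

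Of 20 NRF2 targets, genes of the oxidative stress defence, 7 rose and 7 fell at 72 h (8 and 8 adjusted over the list alone, 0.882). DNA damage signalling and repair genes had 6 of 28 higher and 8 lower (6 and 9 adjusted over the list alone, 0.256), with PRKDC at -1.05, TP53BP1 at -0.87 and ATR at -0.76, all genes of the response to broken or stalled DNA. Nuclear-encoded oxidative phosphorylation had 9 of 40 higher and 5 lower (9 and 5 adjusted over the list alone, 0.822), with COX6A1 at 0.63, not called without bioreactor 1 (0.476, adjusted p = 0.139), and the complex I gene NDUFV1 at -0.55. Hypoxia genes had 5 of 19 higher and 5 lower (5 and 5 adjusted over the list alone, 0.776), with EGLN3 and PFKFB3 at -0.99 and -0.85 and ANKRD37 at 0.99, which was not called without bioreactor 3 (0.682, adjusted p = 0.072). The metallothionein list passed at 72 h (0.0154, and adjusted p = 0.466 with an estimated correlation), with MT2A at -0.76.

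Replication-dependent histone transcripts, higher from 24 h on, were weighed against carry-over of RNA without poly(A) tails and against a larger share of cells in S phase. Carry-over in the 5 libraries rich in rRNA is argued against as the whole cause, since the 7 other later libraries had histone medians of 1.31 to 2.12. The 5 rich libraries stood higher, at 2.42 to 3.05, and RNAs without poly(A) tails were higher there by a median of 4.44. A part of carry-over in the rise of those 5 libraries is left open. S phase genes moved less than the histones at 24 h, with an upper quartile of 0.165 against a lower quartile of 1.84. The 24 h libraries of bioreactors 2 and 3 were rich in rRNA. The lists need not shift equally with the share of cells in S phase, so this does not decide on a larger S phase share. Carry-over in all later libraries cannot be told apart from a rise of histone mRNA, because 5 RNAs without poly(A) tails (RN7SK, RMRP, RPPH1, RN7SL1 and RN7SL2) were higher in the libraries not rich in rRNA too, by a median of 0.67 against 1.74 for the histones. Histone transcripts that gained poly(A) tails may also underlie the pattern, which was not tested.

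A group of genes near silence at 0 h was detected at 72 h, with 56 protein-coding genes going from below 0.1 to above 0.5 CPM and 2 going the other way. They were picked on the mean of the 3 libraries of each time, without a test or a condition on each bioreactor. Single genes may therefore rest on 1 bioreactor. Members of the gene lists, interferon-stimulated genes included, were not set apart. Depth is argued against, since at equal depth the lowest 72 h library still detected 392 more protein-coding genes than the highest 0 h library. Genomic DNA is argued against, since the summed CPM of 392 olfactory receptor genes, silent in most cells, was 1.23 times that at 0 h and at most 1.45 times in a single library. Blood cells are argued against as the source of the whole group, since PTPRC, LYZ and HBB, abundant in white and red blood cells, averaged 0.0594, 0.0826 and 0.101 CPM at 72 h (at most 0.303 in a library). HBA1 was at 0.912 CPM, against 0.366 CPM at 0 h. Other cell types were not searched. A loss of silencing after transfection or with time in culture may underlie the pattern as a hypothesis, and was not tested.

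Other splits of the libraries were counted for each comparison. For the time course, 1 of 100 regroupings of the 24 libraries, the real one, reached 11133 genes and the highest other called 2587. With the times shuffled only within each bioreactor, the real order was again the 1 of 100 that reached this number and the highest other called 10, so chance is excluded at the level of 1 in 100. For each pair of times there are 10 splits, too few for a share under 0.05. The real split and the highest other gave 525 and 0 genes at 3 h, 3962 and 0 at 6 h, 4528 and 0 at 12 h, 3739 and 0 at 24 h, 3572 and 0 at 36 h, 5945 and 1 at 48 h, 9648 and 0 at 72 h, and 4514 and 2085 at 72 h against 24 h, the real split being the 1 that reached its value in each. The split with 2085 genes set both libraries of bioreactor 2 with the 24 h library of bioreactor 1 against both of bioreactor 3 with the 72 h library of bioreactor 1, while the split with the libraries of bioreactor 1 exchanged called 0, so what it follows is open. With the bioreactor block 6411 genes were called. Of the 4 splits that part all 3 bioreactor pairs, the other 3 called no gene in any comparison by edgeR's test.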
